A study of Escherichia coli with 21 samples.

How the data were processed

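The series holds 21 samples of total RNA from Escherichia coli, each hybridised to 1 Affymetrix E. coli Antisense Genome Array, which carries probe sets for genes, for the stretches between genes and for tRNA and rRNA. Per the labels, cells of 7 strains grew with air in M9 glucose medium, a minimal salts medium, RNA was stabilised and extracted during exponential growth, and cDNA was made, labelled and hybridised by the manufacturer's protocols. The strains were a reference strain called wild and 6 knock-out strains (appY, arcA, fnr, oxyR, soxS and the double knock-out of arcA and fnr, called arcAfnr), with 3 arrays each. Group and replicate number were read from the sample titles, and each sample had a group.

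The deposited values are probe set intensity on a linear scale, 1 column per array, made by the authors from the array images. Every column has the same mean of 250.1 after trimming 2% of the probe sets at each end, which shows a scaling of each array to a fixed trimmed mean. The summary algorithm and its software are not given in the sources used here. The 7312 probe sets comprised 4248 of genes, 2886 of intergenic stretches, 97 of tRNA or rRNA and 81 controls. Gene probe set medians ran from 123.4 to 145.6 over the arrays, a range of 18%.

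Because the array medians differed by more than a limit of 5% set in advance, quantile normalization over all probe sets was used. Intensities under a floor of 16.0, the 10th percentile of the gene values, were then set to the floor, and log2 was taken. A gene probe set was tested where it exceeded the floor on at least 3 of the 21 arrays, which left 3970. A fold change is on this floored log2 scale and understates the change of dim genes; where all 3 arrays of a strain lay at the floor it is written as at least N-fold, from the mean log2 value of the brighter strain against the floor.

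Gene names came from the b number of each probe set, matched to a reference table of E. coli genes. That table also gave synonyms for finding list members, which genes neighbour each other, and which probe sets are of tRNA or rRNA. Of the 4248 gene probe sets, 4086 matched and 162 kept the name of the array design. In the platform's own annotation, 3656 probe sets have 1 symbol, 589 several and 181 none. There were 47 gene probe sets that the array design marks as shared by similar sequences, 42 of them tested, and none of these is named.

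Tests were made with limma 3.58.1 in R 4.3.3. A linear model with a mean per strain was fitted to all 21 arrays (14 residual degrees of freedom), and each contrast was tested with a moderated test with an intensity trend, two-sided. The p-values were adjusted by the Benjamini-Hochberg method over the 3970 genes, and a gene is said to have passed, risen or fallen where the limma adjusted p is under 0.05. The 9 comparisons were each knock-out against wild, arcAfnr against arcA, arcAfnr against fnr, and the interaction of arcA and fnr, which asks whether the double knock-out differs from the sum of the single ones. A moderated F test over the 6 knock-out contrasts asked whether any strain differed from wild. Errors of log2 changes are standard errors from this fit, with 3 arrays per strain.

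There were 27 gene lists fixed before the data were examined, covering respiration, fermentation, stress regulons, motility, biosynthesis and uptake of iron, sugars and phosphate; 3 listed members were not found on the array. Lists were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the 27 lists. Camera compares a list with all other genes, so its direction can differ from the sign of the list's median. Beside it stands camera with a correlation estimated from the data. The list test fry, which does not compare a list with other genes, was also run. Its p-values enter only the counts and ranges over alternatives. A list is said to have passed where the adjusted p of camera is under 0.05, so a list that did not pass may still have passed in fry. The number of list members that passed is given over all genes and adjusted over the list alone (written as alone).

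The rule for naming genes, also fixed beforehand, took the targeted genes and the 10 genes that rose most and the 10 that fell most against wild among those that passed and whose 3 values did not overlap wild. It also took up to 4 members of each list tied to the regulator or past the threshold, and the neighbours of the deleted gene. For the other 3 comparisons it took the 5 largest changes in each direction. Genes named outside this rule are said to have been chosen after their values were seen.

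The alternatives were the values as deposited, median scaling, a floor at the 25th percentile and an added constant in place of a floor. Others were no filter on dim probe sets, the dimmest 30% left out, a spread without the intensity trend, a robust spread, a block for the replicate number, a fit with only the strains compared, and leaving out each array in turn. Further alternatives were chosen after the data were seen: array weights, a spread estimated with the third appY array left out, and the estimated correlation with that array left out. Overlaps of comparisons that share the 3 wild arrays were set beside the number for independent lists and beside simulated unchanged strains.

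The steps were tested on simulated data with the real levels and spreads before use. For the comparison of fnr with wild, 55.2% of genes with a simulated log2 change of 0.5, 97% of those with 1 and 100% of those with 2 were recovered among 3970 genes, and 3.4% of the calls were unchanged genes. For the interaction the shares were 14.9%, 79.1% and 97%, with 2.3% unchanged. Changes were given only to genes with a mean log2 level more than 2 above the floor, so the shares recovered do not cover dim genes. A simulated shift of 1 list gave an adjusted p of 1.35e-08, and 0 of the 26 other lists passed. The simulated genes varied independently, whereas the correlation estimated for acid resistance was 0.508 with the third appY array left out. The 0 of 26 therefore does not show how often correlated lists pass falsely at the preset correlation.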

Results

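Gene expression was compared across 7 strains of Escherichia coli grown with air on glucose: a reference strain (wild) and knock-outs of appY, arcA, fnr, oxyR, soxS, and arcA together with fnr (arcAfnr). ArcA and Fnr control genes for growth with and without oxygen, AppY acts on genes of anaerobic energy metabolism, and OxyR and SoxS control defences against peroxide and superoxide. The labels give the response to a change in oxygen supply as the purpose of the study, and all 21 samples analysed here grew aerobically. Each strain had 3 arrays, and this number limits the precision. The labels do not say that the 3 samples of a strain were separate cultures, so the p-values measure the spread between these samples, which may be technical. On each array between 89.1% and 91.3% of the gene probe sets exceeded the floor. The third appY array stood apart, with a mean correlation of 0.929 with its own strain, where no array of another strain was below 0.984.

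The targeted genes were low in their own knock-outs on every array. The intensity of arcA was 53.4 to 68.9 in the arcA strain and 45.7 to 60.6 in arcAfnr, against 223.1 to 531.8 on the other 15 arrays, and its log2 change against wild was -2.16 ± 0.16 in arcA and -2.35 ± 0.16 in arcAfnr. Among the strains that carry arcA it was lowest in wild. It was higher by 0.57 in appY, 0.76 in fnr, 0.76 in oxyR and 0.68 in soxS (limma adjusted p = 0.0288, 0.00535, 0.00256 and 0.0262). The fnr gene read 22.4 to 43.8 in fnr and 25.8 to 36.6 in arcAfnr, against 585.5 to 901.4 elsewhere, with log2 changes of -4.82 ± 0.21 and -4.62 ± 0.21. For oxyR the values were 15.7 to 30 in its knock-out and 186 to 337.5 elsewhere (-3.25 ± 0.18). The soxS gene lay at the floor on all 3 arrays of its knock-out (1 to 4.3, against 80.4 to 231.8 elsewhere) and was at least 9.7-fold lower than in wild (limma adjusted p = 2.03e-07). The appY gene was dim in every strain: it read 0.7 to 2.6 in the appY strain and 10.4 or more on the other 18 arrays, with means of 1.7 and 17.6 (exact permutation test, two-sided p = 0.000752, the smallest that 1330 splits can give). On the floored scale its log2 change of -0.32 ± 0.15 did not pass (adjusted p = 0.143). Of the genes up to 2 places from the deleted ones, ogt next to fnr fell by 0.57 ± 0.13 in fnr (adjusted p = 0.00854). The gene argB, 2 places from oxyR, fell by 1.11 ± 0.27 in oxyR (adjusted p = 0.00818). It belongs to the arginine synthesis list, whose median log2 change was -0.91 in oxyR and -0.6 in fnr, so its fall was not particular to its place. In arcAfnr ogt had a log2 change of -0.41 ± 0.13 (adjusted p = 0.0487), which did not pass in any of the 6 fits without 1 of the arcAfnr or wild arrays (adjusted p up to 0.161, without wild 3).

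**Figure D1:**
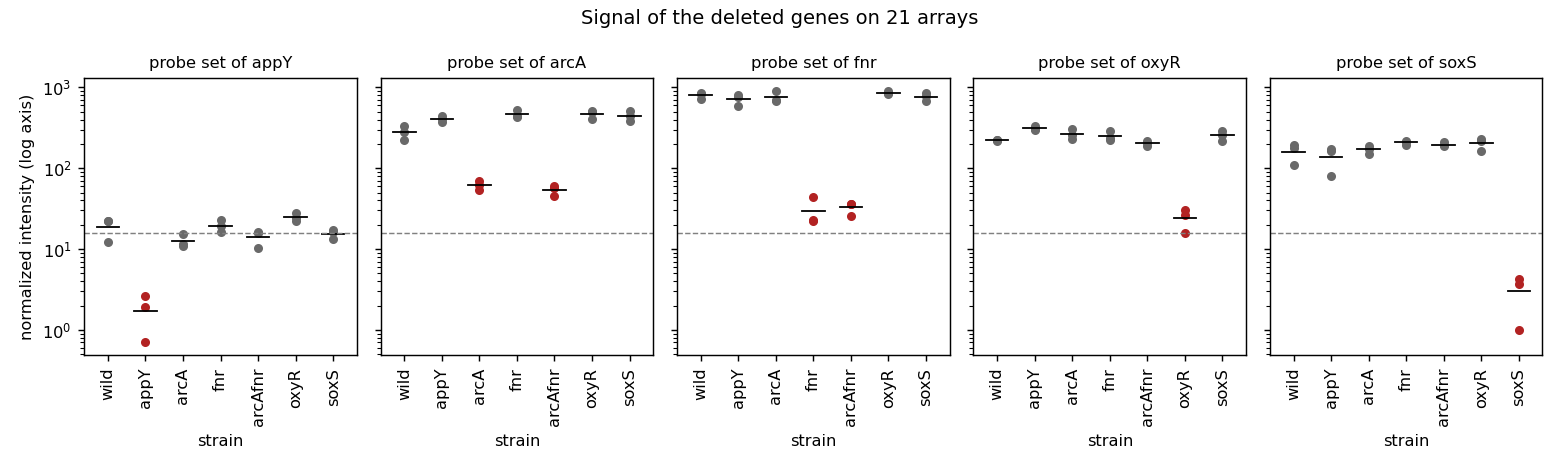
Normalized intensity (log axis) of the probe sets of the 5 deleted genes on all 21 arrays, with 1 point per array, a bar for the mean of each strain and a dashed line at the floor of 16.0; red marks strains that lack the gene. The appY probe set reads 0.7 to 2.6 in its knock-out and 10.4 or more elsewhere, and the other 4 lie lowest in their knock-outs.

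Over the 6 knock-outs together, 985 of 3970 genes differed from wild in at least 1 strain (moderated F test). With 1 array left out this number ran from 742 (without oxyR 2) to 1353 (without appY 3), and array weights gave 1839.

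**Figure D2:**
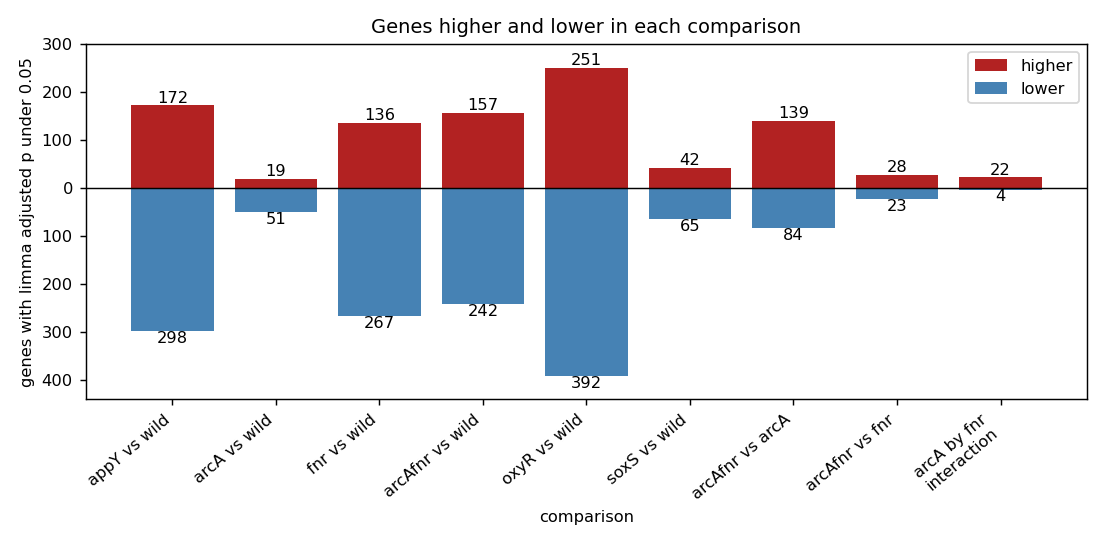
Number of genes with a limma adjusted p under 0.05 in each of the 9 comparisons (3 arrays per strain), with genes that were higher drawn above 0 and genes that were lower drawn below 0. The counts run from 26 for the interaction of arcA and fnr to 643 for oxyR against wild.

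In the appY strain genes for iron uptake rose: 28 of the 30 tested members of the iron acquisition list passed (30 adjusted over the list alone), with a median log2 change of 1.28. The genes entC and entE, for enzymes that make the iron carrier enterobactin, rose by 2.63 ± 0.10 and 2.69 ± 0.12, and fepA, for its outer membrane receptor, by 2.59 ± 0.12. The genes nrdE and nrdI of the manganese-dependent ribonucleotide reductase rose by 3.90 ± 0.34 and 2.41 ± 0.17. Among the genes that fell were flu, for the surface protein antigen 43 (-2.41 ± 0.12), the nearby yeeR (-1.53 ± 0.20), and ydfT, which was at least 2.56-fold lower. The iron list passed in camera (adjusted p = 1.08e-46, and adjusted p = 0.00033 with an estimated correlation).

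The lists tied to AppY are hydrogenase 1, made from the hya operon, and the bd oxidases, terminal oxidases used at low oxygen. None of the 6 hya genes passed, alone or adjusted over the list alone, with a median log2 change of 0.63 and a list adjusted p of 0.0275 (adjusted p = 0.483 with an estimated correlation). None of the 5 bd oxidase genes passed either (adjusted p = 0.501), and the median of -0.10 and the mean of 0.22 differed in sign. The third appY array had list medians of 2.14 for hydrogenase 1 and 0.51 for the bd oxidases against wild, where the first and second had 0.06 and -0.15 for hydrogenase 1 and -0.16 and -0.28 for the bd oxidases. Without that array the hydrogenase 1 list had a median of -0.02 and did not pass (adjusted p = 0.989), nor did it pass without wild 1 (adjusted p = 0.0689).

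Other lists moved with the same array. Its median against wild was -5.13 for the cyo oxidase genes, -2.10 for the tricarboxylic acid (TCA) cycle and glyoxylate genes, -2.96 for arginine synthesis, -1.28 for pyrimidine synthesis, 1.05 for fermentation and 2.22 for acid resistance. With all arrays, the lower lists were the TCA cycle (2 of 19 members, 11 adjusted over the list alone), arginine synthesis (1 of 12, alone 11), pyrimidine synthesis (1 of 8, alone 6) and sulfur assimilation (4 of 16 lower and 1 higher, alone 8 and 1). The SoxRS regulon (6 of 26, alone 7), purine synthesis (3 of 13 lower and 1 higher, alone 6 and 1) and tryptophan synthesis (2 of 5, alone 3) were lower too. So were the cyo oxidase (0 of 5, alone 4), the nuo genes (0 of 13, alone 0) and acid and fat oxidation (1 of 26, alone 0). The higher lists were anaerobic respiration (3 of 45, alone 0), fermentation (2 of 14, alone 2), the other hydrogenases and nickel uptake (3 of 29, alone 4), the RpoS stress genes (3 of 24, alone 3) and acid resistance (3 of 14, alone 11). None of these lists passed with an estimated correlation: the adjusted p was 0.495 for the TCA cycle, 0.328 for SoxRS, 0.498 for cyo, 0.62 for the nuo and acid and fat oxidation lists, and 0.483 for the others. With the preset correlation their adjusted p ran from 1.23e-06 (acid resistance) to 0.0451 (cyo). Without the third appY array the acid resistance list (adjusted p = 0.000543) and the arginine list (0.0161) still passed in camera, but not with an estimated correlation (adjusted p = 0.619 for both), and the iron list passed in both (7.17e-62 and 8.7e-05, with 27 members higher). The other lists did not pass without it: the adjusted p was 0.122 for the TCA cycle, 0.385 for cyo and purine synthesis, 0.592 for nuo, and 0.388 for acid and fat oxidation. It was 0.2 for pyrimidine synthesis, 0.176 for tryptophan synthesis, 0.267 for sulfur assimilation and 0.105 for SoxRS. For the higher lists it was 0.0819 for anaerobic respiration, 0.171 for fermentation, 0.0578 for the other hydrogenases and 0.216 for RpoS. Some calls were also lost without wild 1 (cyo 0.102, nuo 0.136, acid and fat oxidation 0.0639, purine 0.0689, tryptophan 0.0914) or wild 2 (cyo 0.0534, nuo 0.118).

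**Figure D3:**
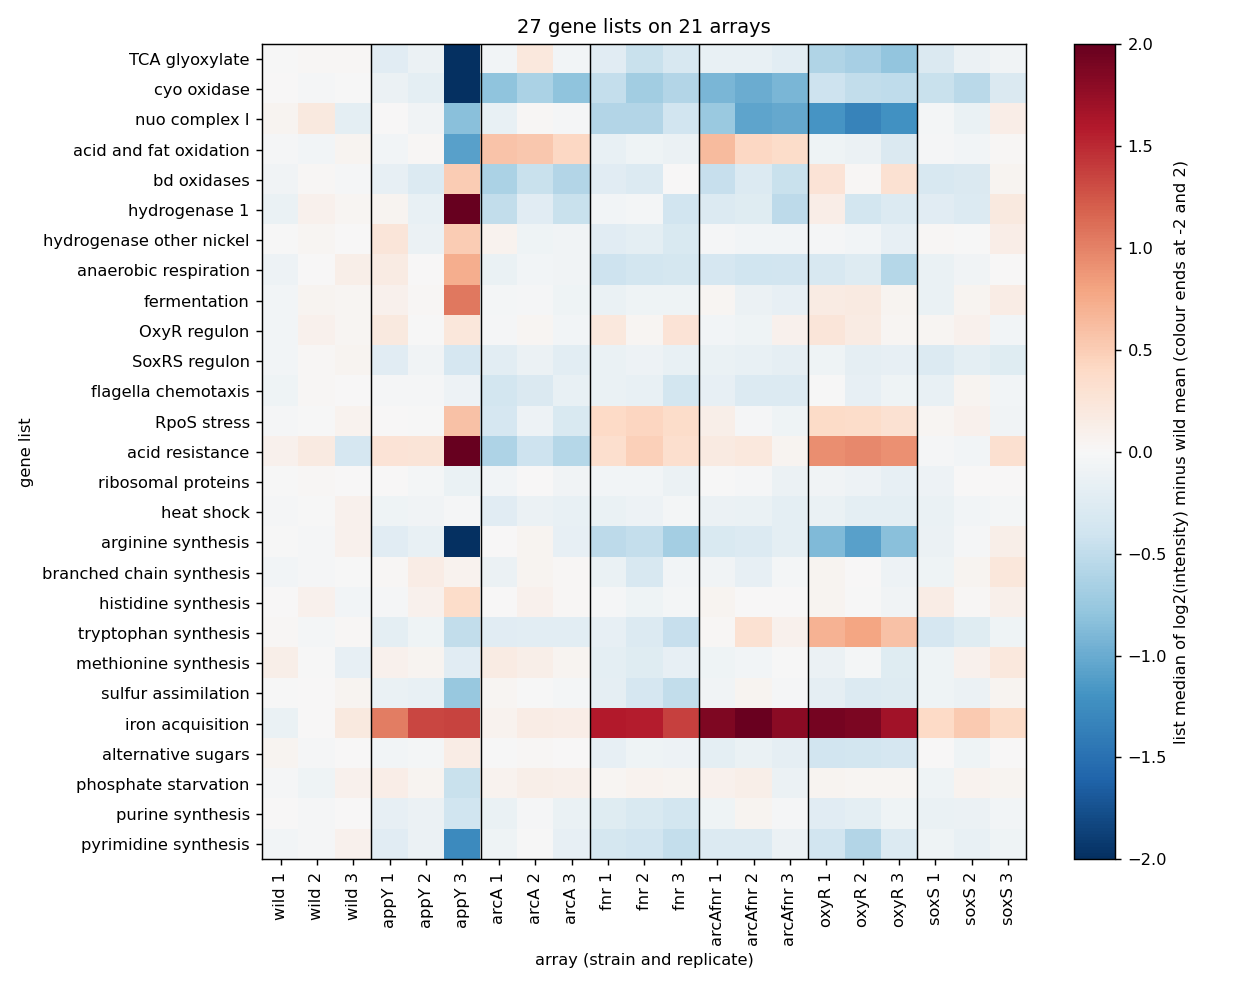
Median over each of the 27 gene lists of log2 intensity minus the wild mean, drawn as colour for each of the 21 arrays (colour ends at -2 and 2). Iron acquisition lies at 1.02 or above on the 12 arrays of appY, fnr, arcAfnr and oxyR and at 0.53 or below on the 9 arrays of wild, arcA and soxS, and the third appY array stands apart from the other appY arrays.

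In total 470 genes passed in appY, 172 higher and 298 lower, and 75 of them changed over 2-fold; 36.6% were higher, against 52.5% with median scaling. The count was 220 without appY 3 (87 higher and 133 lower, 185 of them also among the 470 in the same direction), 780 without appY 1, 213 without wild 2 and 170 without wild 3, and 23 in a fit with only the strains compared; array weights gave 214. Leaving out each array in turn was planned, while array weights were chosen after the data were seen. Of the 54 named genes that passed, 21 did so in every fit without 1 array.

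In the arcA strain genes for the oxidation of organic acids and fatty acids rose, 6 of 26 tested members (12 adjusted over the list alone), with a median log2 change of 0.49. The fatty acid activation gene fadD rose by 0.96 ± 0.09, and glcB and glcG of the glycolate operon, where glcB makes malate synthase G, rose by 1.0 ± 0.12 and 0.63 ± 0.10. These 3 passed in every fit without 1 array. The glycolate gene glcF rose by 0.73 ± 0.13 (adjusted p = 0.058 without arcA 3). The genes glcD (1.38 ± 0.32) and fadA (0.73 ± 0.17) passed with all arrays but in none of the 6 fits without 1 arcA or wild array (adjusted p up to 0.101 and 0.124, both without arcA 3). The list passed in camera (adjusted p = 2.73e-14) but not with an estimated correlation (adjusted p = 0.468); with the third appY array left out of that fit it passed (adjusted p = 0.00111), and 13 members were higher with that array left out of the spread.

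The other lists tied to ArcA gave no call in the arcA strain with all arrays. No member passed for the TCA cycle (0 of 19, median 0.04, adjusted p = 0.194) or for complex I of the nuo operon (0 of 13, median -0.03, adjusted p = 0.588, with a test that pointed up). Nor did any for the cyo oxidase (0 of 5, median -0.74, adjusted p = 0.555) or for the bd oxidases (0 of 5, alone 1 lower, median -0.61, adjusted p = 0.102). With the third appY array left out of the spread, all 5 cyo genes passed as lower and the list passed too (adjusted p = 3.45e-10, and adjusted p = 0.0106 with an estimated correlation); over all alternatives the adjusted p of the list ran from 3.45e-10 to 0.863. A smaller fall of cyo was seen in that fit in 3 strains that carry arcA, so it was not particular to loss of arcA. The median was -0.49 in fnr (5 of 5 lower), -0.47 in oxyR (4 of 5) and -0.41 in soxS (4 of 5). In appY it was -0.13, with 0 of 5 lower. In that fit the bd oxidases were lower (3 of 5, adjusted p = 0.00237, with an estimated correlation adjusted p = 0.2, range over alternatives 0.00227 to 0.779). The TCA cycle tested higher with 0 members past the threshold (adjusted p = 0.0362, with an estimated correlation adjusted p = 0.497, range over alternatives, fry included, 0.0112 to 0.97). The genes yahC and ynbE, of unknown function, fell by 1.87 ± 0.30 and 0.97 ± 0.16 and passed in every fit without 1 array. Of the iron list 4 of 30 rose (4 adjusted over the list alone), among them entC by 0.62 ± 0.10 (adjusted p = 0.00513); the list adjusted p was 2.35e-06, and 0.468 with an estimated correlation.

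Lists of stress and motility genes were lower in camera. They were acid resistance (1 of 14, alone 1, adjusted p = 0.0166), the RpoS genes (1 of 24, alone 4, adjusted p = 0.0245) and flagella and chemotaxis (3 of 47, alone 7, adjusted p = 0.0245). With an estimated correlation the adjusted p was 0.779, 0.779 and 0.575. In the fit with the third appY array left out of the spread, 10 of 14 acid resistance genes, 6 of 24 RpoS genes and 6 of 47 flagella genes were lower (adjusted p = 2.51e-08, 0.00278 and 0.0403). With an estimated correlation the adjusted p was then 0.2, 0.391 and 0.441. Acid resistance lost its call without wild 1 (0.137) or wild 2 (0.113). The RpoS list lost it without arcA 1 (0.0623), arcA 3 (0.0794) or wild 2 (0.0684), the flagella list without arcA 1 (0.0582), arcA 2 (0.14) or wild 2 (0.113). The methionine and phosphate lists were higher with 0 members past the threshold over all genes or alone (adjusted p = 0.0182 and 0.0393), and neither passed with an estimated correlation (adjusted p = 0.575 and 0.724). Methionine synthesis lost its call without arcA 1 (0.112), wild 2 (0.0684) or wild 3 (0.112), and phosphate starvation without arcA 2 (0.129), arcA 3 (0.0601), wild 1 (0.116) or wild 2 (0.198).

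Altogether 70 genes passed in arcA, 19 higher and 51 lower (27.1% higher, 62.5% with median scaling and 18.5% with the deposited values), 7 of them over 2-fold, and the deposited values gave 119 genes. The count was 21 without arcA 1, 17 without arcA 3, 46 without wild 1, 38 without wild 2 and 19 without wild 3, and 8 of the 30 named genes that passed did so in each of the 6 fits without 1 array. It was 286 with the third appY array left out of the spread and 576 with array weights.

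In the fnr strain iron uptake genes rose, 25 of 30 (28 adjusted over the list alone), with a median log2 change of 1.51. The largest rises were those of nrdE (4.86 ± 0.34), the enterobactin gene entA (4.43 ± 0.37) and fiu, for an outer membrane receptor of iron-bound catechols (4.28 ± 0.62), and cirA, for another such receptor, rose by 3.18 ± 0.21. The gene sodB, for the iron superoxide dismutase, fell by 3.10 ± 0.23. The gene grcA, which Fnr is known to activate and which replaces part of an oxygen-damaged formate-lyase, fell by 2.32 ± 0.37. The trimethylamine oxide reductase gene torA fell by 0.58 ± 0.13. The iron list passed with both correlations (adjusted p = 1.94e-61 preset, and adjusted p = 6.78e-05 with an estimated correlation).

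Of the lists tied to Fnr, anaerobic respiration had 4 of 45 members lower (alone 4), fermentation 2 of 14 (alone 2) and the other hydrogenases and nickel uptake 0 of 29 (alone 0), and none passed as a list in camera with all arrays (adjusted p = 0.0797, 0.616 and 0.562). With the third appY array left out of the spread, anaerobic respiration passed as lower (13 of 45 lower and 1 higher, adjusted p = 0.0136, with an estimated correlation adjusted p = 0.374, range over alternatives 0.000975 to 0.732). This fall was not particular to strains that lack fnr. In that fit the list median was -0.38 in fnr. It was also -0.38 in oxyR, which carries fnr, with 13 of 45 members lower (camera adjusted p = 0.00943). The dimethyl sulfoxide reductase gene dmsA was at least 3.01-fold lower (adjusted p = 0.033) but passed in none of the 6 fits without 1 fnr or wild array (adjusted p up to 0.091, without fnr 3). The log2 change of dmsA was -1.59 in fnr, arcAfnr and oxyR alike. The nitrate reductase gene napH fell by 1.53 ± 0.38 (adjusted p = 0.0636 without fnr 1 and 0.0672 without wild 3), and pflA, for the activator of formate-lyase, by 0.52 ± 0.12 (adjusted p = 0.0678 without wild 2 and 0.0629 without wild 3). The OxyR list was higher, with 8 of 19 members higher and 1 lower (alone 8 and 1), among them sufA (1.58 ± 0.12) and sufB (1.59 ± 0.14) for building iron-sulfur clusters and fhuF (1.55 ± 0.10); Fur, the iron regulator, is known to repress these too. That list passed with an estimated correlation (adjusted p = 0.0341), but not with the third appY array left out of that fit (adjusted p = 0.0532).

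Other lists also passed in fnr with the preset correlation. The RpoS list was higher (8 of 24, alone 10, adjusted p = 3.18e-10, with an estimated correlation adjusted p = 0.247), with kbp at 0.53 ± 0.12. Purine synthesis was lower (5 of 13, alone 9, adjusted p = 0.00158, with an estimated correlation adjusted p = 0.61), with purE at -0.49 ± 0.09. The nuo genes were lower (2 of 13, alone 9, adjusted p = 0.00158, with an estimated correlation adjusted p = 0.732). Acid resistance was higher with 0 of 14 members past the threshold (alone 0, adjusted p = 0.00149, with an estimated correlation adjusted p = 0.732; 0.0514 without wild 3). Sulfur assimilation was lower (5 of 16, alone 6, adjusted p = 0.0425, with an estimated correlation adjusted p = 0.732), a call lost with the deposited values and with median scaling, and without fnr 2 (0.0938), fnr 3 (0.078), wild 1 (0.0978) or wild 3 (0.055). Members past the threshold with the third appY array left out of the spread were 12 for RpoS, 9 for purine synthesis, 11 for nuo, 6 for acid resistance and 9 for sulfur assimilation. The adjusted p was then 1.32e-11, 0.000473, 2.07e-05, 5.91e-07 and 0.000252, and with an estimated correlation adjusted p = 0.0532, 0.119, 0.22, 0.182 and 0.137.

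Against wild 403 genes passed in fnr, 136 higher and 267 lower (33.7% higher, 64.4% with median scaling), 66 of them over 2-fold. The count was 236 without fnr 2, 191 without fnr 3 and 206 without wild 3, and 25 of the 45 named genes that passed did so in every fit without 1 array. It was 820 with the third appY array left out of the spread and 849 with array weights.

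In the double knock-out arcAfnr 27 of 30 iron uptake genes rose (30 adjusted over the list alone), with entA at 4.95 ± 0.37, entC at 3.49 ± 0.10 and nrdE at 4.96 ± 0.34. All 13 tested nuo genes, for the proton-pumping NADH dehydrogenase, fell (13 adjusted over the list alone), with nuoN at -1.22 ± 0.16 and nuoE at -0.85 ± 0.15. The genes sodB and grcA fell by 3.90 ± 0.23 and 2.76 ± 0.37, and pflA fell by 1.15 ± 0.12. The dipeptide transporter gene dppD fell by 1.50 ± 0.14 and mrp, which handles iron-sulfur clusters, by 1.52 ± 0.13. The fatty acid and glycolate genes that rose in arcA were also higher here: fadD by 0.66 ± 0.09, glcB by 0.72 ± 0.12 and glcG by 0.48 ± 0.10.

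The iron list passed with both correlations (adjusted p = 3.95e-63, and adjusted p = 5.76e-05 with an estimated correlation). The nuo list had an adjusted p of 6.79e-11, with an estimated correlation adjusted p = 0.31, or 0.0414 with the third appY array left out. The acid and fat oxidation list was higher (5 of 26, alone 8, adjusted p = 9.47e-06, with an estimated correlation adjusted p = 0.587, or 0.0253 without the third appY array). In the OxyR list 8 of 19 members were higher and 1 lower (alone 8 and 2), with mntH at 2.70 ± 0.19 for manganese uptake; its median was -0.03 although the test pointed up (adjusted p = 1.72e-05, with an estimated correlation adjusted p = 0.13). Anaerobic respiration was lower (4 of 45 lower and 1 higher, alone 5 and 1, adjusted p = 0.0343, with an estimated correlation adjusted p = 0.828), a call lost without arcAfnr 1 (0.0614), wild 1 (0.0604) or wild 2 (0.0622). In that list napC fell by 0.97 ± 0.20 and nrfB, at the floor in wild, was at least 1.76-fold higher. Flagella and chemotaxis were lower (6 of 47 lower and 1 higher, alone 6 and 1, adjusted p = 0.0252, with an estimated correlation adjusted p = 0.39; 0.061 without wild 2). In it flgD stood at -1.0 ± 0.14 and the master regulator genes flhC at -0.55 ± 0.11 and flhD at -0.73 ± 0.15. The TCA cycle, cyo and bd oxidase, fermentation and other hydrogenase lists did not pass with all arrays (adjusted p = 0.925, 0.508, 0.218, 0.532 and 0.954). With the third appY array left out of the spread, the cyo oxidase passed as lower (5 of 5, adjusted p = 2.16e-08, with an estimated correlation adjusted p = 0.0251, range over alternatives 2.16e-08 to 0.983). So did the TCA cycle (7 of 19, 0.0239, with an estimated correlation adjusted p = 0.505, range 0.0239 to 0.987) and the bd oxidases (2 of 5, 0.0168, with an estimated correlation adjusted p = 0.23, range 0.0168 to 0.896). In the same fit 14 acid and fat oxidation genes were higher and 1 lower, and 13 anaerobic respiration genes were lower and 3 higher (adjusted p = 9.31e-08 and 0.00382, with an estimated correlation adjusted p = 0.0253 and 0.306).

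In arcAfnr 399 genes passed, 157 higher and 242 lower (39.3% higher, 51.9% with median scaling and 25% with the deposited values), 98 of them over 2-fold. The count was 187 without arcAfnr 2, 247 without arcAfnr 3, 257 without wild 2 and 211 without wild 3, and 38 of the 45 named genes that passed did so in every fit without 1 array. The same alternatives gave 681 and 691.

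Loss of fnr in a strain that already lacked arcA was read from arcAfnr against arcA. The gene entA was higher by 5.01 ± 0.37, nrdE by 4.06 ± 0.34 and fiu by 3.82 ± 0.62, and sodB fell by 3.54 ± 0.23, grcA by 3.24 ± 0.37 and mrp by 1.37 ± 0.13. All 11 named genes passed in every fit without 1 array. In total 223 genes passed, 139 higher and 84 lower (62.3% higher, 49.3% with median scaling), 73 of them over 2-fold. The count was 142 without arcA 1, 136 without arcA 3, 142 without arcAfnr 1 and 128 without arcAfnr 2. It was 424 with the third appY array left out of the spread and 773 with array weights.

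Loss of arcA in a strain that lacked fnr, read from arcAfnr against fnr, raised fadD by 0.92 ± 0.09, pdeL by 1.28 ± 0.17, mhpC of phenylpropionate breakdown by 0.96 ± 0.13 and astE of arginine breakdown by 1.04 ± 0.15. The acylphosphatase gene yccX fell by 0.95 ± 0.16, and yjjY, beside arcA, by 0.93 ± 0.16 (adjusted p = 0.0539 without fnr 3). Here 51 genes passed, 28 higher and 23 lower (54.9% higher, 34.4% with median scaling and 37% with the deposited values), 5 of them over 2-fold. The count was 12 without arcAfnr 2, 28 without arcAfnr 3, 20 without fnr 1 and 13 without fnr 3, and between 79 and 138 with the deposited values (81), median scaling (93), the higher floor (79) or only the strains compared (138). It was 295 with the third appY array left out of the spread and 429 with array weights. Of the 11 named genes that passed, 6 did so in every fit without 1 array.

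The interaction asked whether the double knock-out departed from the sum of the single ones. The genes trpE and trpD of tryptophan synthesis were higher than the sum by 0.95 ± 0.18 and 0.70 ± 0.14, yahC by 2.62 ± 0.43, ddpD by 1.16 ± 0.24, ybdG by 1.03 ± 0.20 and dgcI by 1.0 ± 0.20. The genes yjjY (-1.01 ± 0.23), rmuC (-0.84 ± 0.19), btuD (-0.79 ± 0.18) and dfp (-0.62 ± 0.13) were lower than the sum. Each of these 10 genes lost its call without arcA 1, arcA 3, arcAfnr 1, arcAfnr 2, fnr 2, fnr 3 or wild 3 (adjusted p up to 0.16, for yjjY without fnr 3). A shift of the wild arrays alone would also give such departures, and dgcI was lower and btuD and dfp higher in all 6 knock-outs. Tryptophan synthesis (2 of 5 higher, alone 5, adjusted p = 3.76e-05) and purine synthesis (0 of 13, alone 1 higher, adjusted p = 0.00402) were higher than the sum as lists. The nuo genes (0 of 13, alone 0, adjusted p = 3.86e-06) and the RpoS genes (0 of 24, alone 0, adjusted p = 2.94e-05) were lower. Alternative sugars (0 of 35, alone 0, adjusted p = 0.00507) and acid and fat oxidation (0 of 26, alone 0, adjusted p = 0.015) also tested lower, the latter with a median of 0.01 and a mean of -0.07. With an estimated correlation the adjusted p was 0.241 for the tryptophan and sugar lists, 0.559 for the purine, nuo and RpoS lists and 0.996 for acid and fat oxidation, which also lost its call without wild 2 (0.0841). There 4 of 5 tryptophan, 2 of 13 purine, 1 of 13 nuo and 1 of 24 RpoS genes passed with the third appY array left out of the spread, and with an estimated correlation the adjusted p of these lists was 0.159, 0.159, 0.159 and 0.189.

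Of 3970 genes 26 passed for the interaction, 22 higher and 4 lower (84.6% higher), but 1 with a spread without trend and 4 with median scaling (25% higher), where the median of all genes moved from 0.14 to -0.01. The count was 46 with the higher floor, 88 with only the strains compared, 119 with the third appY array left out of the spread and 340 with array weights. None of the 26 passed in every fit without 1 array. The count was 0 without arcA 1, arcAfnr 1, arcAfnr 2, fnr 3 or wild 3 and 1 without arcA 3 or fnr 2. It was 2 without arcAfnr 3, 6 without fnr 1, 11 without wild 1, 13 without wild 2 and 44 without arcA 2. With all arrays 668 genes had an unadjusted p under 0.05.

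In the oxyR strain 27 of 30 iron uptake genes rose (29 adjusted over the list alone), with entA at 4.81 ± 0.37 and fepA at 3.47 ± 0.12, and nrdE rose by 5.43 ± 0.34. Of the OxyR list 9 of 19 members rose (alone 9 higher and 2 lower): flu, which OxyR is known to repress, by 2.38 ± 0.12, mntH by 3.30 ± 0.19, fhuF by 1.70 ± 0.10 and the 6 suf genes, with sufA at 2.16 ± 0.12. The peroxide defence genes of the same list did not pass with all arrays, with katG (catalase) at -0.65 ± 0.25, ahpC (peroxidase) at -0.25 ± 0.09, dps at 0.09 ± 0.10 and grxA at -0.06 ± 0.15; these 4 were chosen after their values were seen. With the third appY array left out of the spread, 9 members of the OxyR list passed as higher and 2 as lower. The copper and silver efflux genes fell, cusF by 3.30 ± 0.19, cusC by 2.97 ± 0.17, cusB by 2.14 ± 0.21 and cusA by 2.12 ± 0.22, and sodB fell by 4.10 ± 0.23. All 13 nuo genes fell (13 adjusted over the list alone), with nuoH at -1.70 ± 0.22.

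The OxyR list passed with both correlations (adjusted p = 6.29e-10, and adjusted p = 0.0087 with an estimated correlation), as did the iron list (9.39e-49 and 0.000259). A rise of the OxyR list was not particular to this strain. It was also higher in fnr and arcAfnr, where the 6 suf genes rose as well (1.24 to 1.59 and 1.38 to 1.87) but flu fell. Genes for sugars other than glucose were lower, 14 of 35 (alone 16 lower and 1 higher), and the list passed with both correlations too (2.09e-05 and 0.0087). Its members gatB of galactitol uptake, lamB for the maltose porin and mglC of galactose uptake fell by 1.10 ± 0.11, 0.99 ± 0.12 and 1.44 ± 0.19. The nuo list had an adjusted p of 3.99e-13, with an estimated correlation adjusted p = 0.118, or 0.0262 without the third appY array. All 5 tryptophan synthesis genes rose (alone 5), with trpD at 0.76 ± 0.10 (adjusted p = 2e-06, with an estimated correlation adjusted p = 0.0658, or 0.0431 without the third appY array).

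The TCA cycle list was lower in oxyR (4 of 19, alone 8, adjusted p = 0.0281, with an estimated correlation adjusted p = 0.839; 0.056 without oxyR 3 and 0.0583 without wild 1). Its member fumA fell by 1.83 ± 0.47, while sdhA (-1.91 ± 0.62) and sdhB (-2.21 ± 0.69) of succinate dehydrogenase passed in none of the 6 fits without 1 array (adjusted p up to 0.115 and 0.11, both without oxyR 2). Arginine synthesis was lower (3 of 12, alone 3, adjusted p = 0.00327, with an estimated correlation adjusted p = 0.722, or 0.0244 without the third appY array). Acid resistance was higher (4 of 14, alone 12, adjusted p = 8.01e-06, with an estimated correlation adjusted p = 0.556), with the glutamate decarboxylase gene gadB at 1.13 ± 0.25. The RpoS list was higher too (9 of 24, alone 12, adjusted p = 8.4e-06, with an estimated correlation adjusted p = 0.391), with sodC at 0.71 ± 0.13. The ribosomal protein list was lower by a small amount (5 of 54, alone 4, median -0.11, adjusted p = 0.0159, with an estimated correlation adjusted p = 0.722; 0.0738 without oxyR 3 and 0.0539 without wild 1). Anaerobic respiration was lower (3 of 45, alone 0, adjusted p = 0.0372, with an estimated correlation adjusted p = 0.722; 0.134 without oxyR 3, 0.0559 without wild 1 and 0.059 without wild 2). Leaving the third appY array out of the spread, 13 TCA cycle, 12 arginine, 11 ribosomal protein and 13 anaerobic respiration genes were lower, and 13 acid resistance and 15 RpoS genes were higher. The adjusted p of these lists was then 5.03e-09, 1.27e-12, 0.0134, 0.00943, 4.53e-11 and 1.84e-06. With an estimated correlation it was 0.0842, 0.0244, 0.464, 0.296, 0.0748 and 0.0842.

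In oxyR 643 genes passed, 251 higher and 392 lower (39% higher, 48.6% with median scaling and 44.2% with the deposited values), 144 of them over 2-fold. The count was 375 without oxyR 2, and 44 of the 59 named genes that passed did so in every fit without 1 array. It was 984 with the third appY array left out of the spread and 1104 with array weights.

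In the soxS strain ydbK, for a pyruvate-flavodoxin oxidoreductase that SoxS is known to activate, fell by 1.08 ± 0.15 and the flavodoxin gene fldA by 0.34 ± 0.07. Of the SoxRS list 5 of 26 members fell (7 adjusted over the list alone), among them fpr, for ferredoxin reductase, by 0.67 ± 0.14 (adjusted p = 0.0711 without soxS 1). The list members sodA (-0.01 ± 0.43), zwf (-0.33 ± 0.11) and fumC (-0.43 ± 0.52), chosen after their values were seen, did not pass. Iron uptake genes rose here as well, 10 of 30 (15 adjusted over the list alone), with a median of 0.40 and with entC at 1.20 ± 0.10 and fepA at 0.90 ± 0.12, and nrdE rose by 1.79 ± 0.34. The fimbrial gene fimI fell by 0.86 ± 0.16, the cytochrome c maturation gene ccmC by 1.63 ± 0.32 and yahC by 1.92 ± 0.30.

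The SoxRS list had an adjusted p of 0.0198, with an estimated correlation adjusted p = 0.141, and 0.0901 without wild 2; the iron list passed with both correlations (6.31e-19 and 0.0269). In soxS 107 genes passed, 42 higher and 65 lower (39.3% higher, 66.7% with median scaling), 12 of them over 2-fold. The count was 68 without soxS 1, 59 without soxS 3 and 48 without wild 3, 17 with only the strains compared, 250 with the third appY array left out of the spread and 175 with array weights. Of the 25 named genes that passed, 17 did so in every fit without 1 array.

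**Figure D4:**
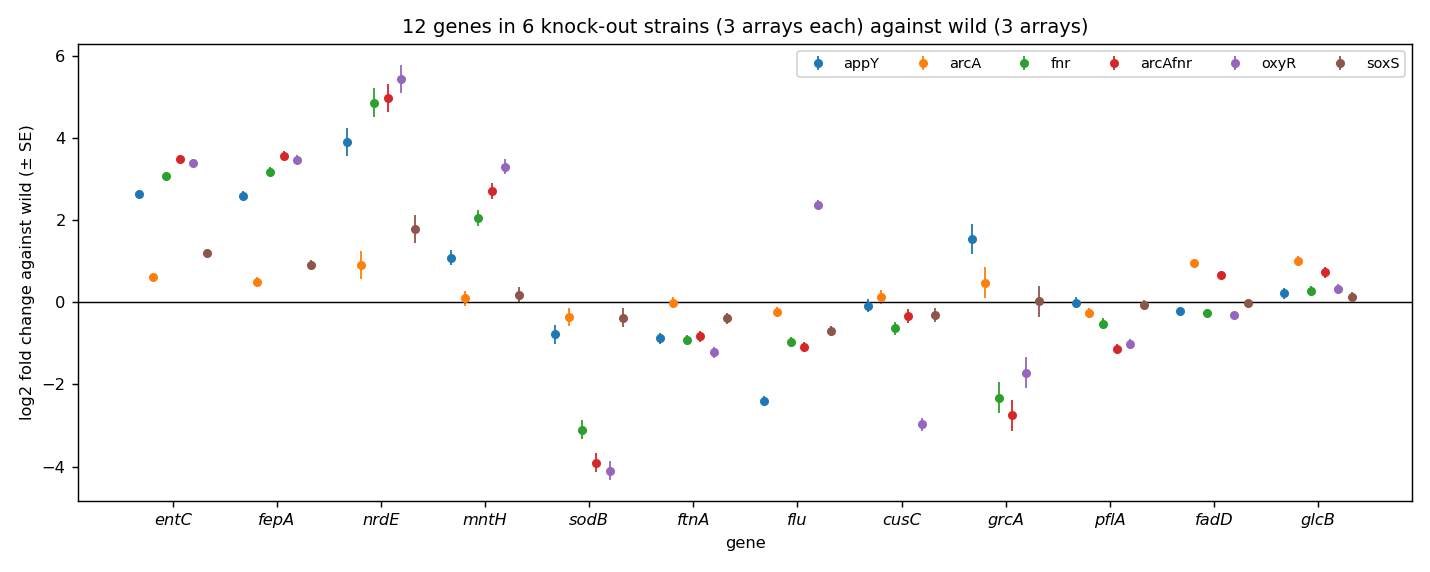
Log2 fold change against wild (points, with standard errors as bars) of 12 genes in the 6 knock-out strains, from the fit to 21 arrays with 3 per strain. The genes entC, fepA and nrdE lie above 0 in all 6 strains, sodB is lowest in fnr (-3.10), arcAfnr (-3.90) and oxyR (-4.10), flu is raised in oxyR and cusC is lowest in oxyR.

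In total 522 genes passed in the same direction in at least 2 knock-outs (262 without wild 3, 336 without wild 2 and 847 without appY 3). Of the genes past the threshold, 188 were higher and 335 lower in at least 2 knock-outs, where independent lists would give 54.5 and 149. The iron receptor and enterobactin genes cirA, entC, entE and fepA were higher in all 6 knock-outs, as were btuD, btuE, dfp and greB, 8 genes against 7.46e-07 for independent lists. There were 4 genes lower in all 6 (dgcI, rlmI, dnaX and torT), against 2.54e-05. In arcA the calls of cirA, entE and fepA rested on all arrays: without arcA 3 the adjusted p was 0.126 for cirA and 0.101 for entE and fepA, and they were also lost without arcA 1, arcA 2, wild 1 or wild 2. The call of greB in arcA was lost without arcA 1 (0.0879), arcA 2 (0.059), arcA 3 (0.0928), wild 2 (0.0723) or wild 3 (0.143). These numbers of genes in all 6 strains were not refitted without 1 array. Unchanged strains simulated against the same 3 wild arrays gave 0 such genes in 20 simulations, but they have few calls to share, so this does not test the overlap. For fnr and oxyR, 107 genes were higher in both and 152 lower in both, against 8.6 and 26.4 for independent lists, and the covariance of their log2 changes across genes was 0.17, against 0.02 simulated. For arcA the correlation was 0.24 with oxyR, 0.33 with appY, 0.37 with fnr and 0.46 with arcAfnr, under the 0.50 that unchanged strains sharing the wild arrays gave, and 0.67 with soxS. The covariances, in the same order, were 0.0336, 0.039, 0.0432, 0.0588 and 0.0529, each above its simulated value, the highest of which was 0.0197. For arcA and oxyR 63.6% of genes had the same sign, against 66.7% simulated. Part of each excess may come from the shared wild arrays, which cannot be split with 3 of them.

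Some lists did not pass in camera against wild in any strain: histidine synthesis (lowest adjusted p = 0.0602, in appY), heat shock (0.0823, in oxyR) and branched-chain amino acid synthesis (0.103, in appY). With the third appY array left out of the spread further lists not tied to the deleted gene passed as lower. In fnr these were the TCA cycle (11 of 19, adjusted p = 0.000123), cyo (5 of 5, 0.000123), arginine (11 of 12, 1.53e-07), pyrimidine (6 of 8, 0.00746) and tryptophan synthesis (2 of 5, 0.0498). In arcAfnr they were arginine synthesis (5 of 12, 0.00316) and alternative sugars (12 of 35, 0.0257). In oxyR they were cyo (4 of 5, 0.00257), sulfur assimilation (6 of 16 lower and 1 higher, 0.00339) and pyrimidine synthesis (4 of 8, 0.00339), and in soxS cyo (4 of 5, 0.000232). With an estimated correlation none of these passed (adjusted p from 0.0726 to 0.39). Genes whose 3 knock-out values did not overlap the 3 wild values made up between 24.6% (soxS) and 37.8% (oxyR) of those tested, where chance gives 10%.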

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

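The tests on the iron genes and on appY replicate 3 were chosen only after the result was seen.

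The effect of losing both regulators differed from the sum of the single losses for 26 genes, and these values stood out because of that test. The log2 departures were 2.62 for yahC, 1.16 for ddpD, 1.03 for ybdG, 1.0 for dgcI, 0.95 for trpE, -1.01 for yjjY, -0.84 for rmuC, -0.79 for btuD and -0.62 for dfp. The contrast also holds the wild arrays, so a gene shifted in wild alone departs from the sum without a joint effect of both losses. Of the genes listed here, dgcI was lower and btuD and dfp were higher in all 6 knock-outs, with departures of opposite sign. Such a shift was not told apart from a joint effect. The list tests gave limma adjusted p values of 3.86e-06 for nuo, 0.015 for acid and fat oxidation, 2.94e-05 for RpoS, 3.76e-05 for tryptophan synthesis, 0.00507 for alternative sugars and 0.00402 for purine synthesis. None of these lists passed with an estimated correlation (adjusted p = 0.559 for nuo, RpoS and purine synthesis, 0.996 for acid and fat oxidation, 0.241 for tryptophan synthesis and sugars). Of 100 regroupings of the 12 arrays, the real one included, 1 gave as many genes, with 3 genes as the highest of the others. Such regroupings move the differences between strains into the spread, so they cannot show whether chance gave this count. The count was 4 with median scaling, 1 with a spread without trend and 0 without wild 3, and no single gene is put forward.

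Probe sets outside the gene comparison were also higher than in wild in some strains. Of 97 tRNA and rRNA probe sets, 34 were higher in arcA, 17 in fnr, 1 in arcAfnr, 1 in oxyR and 24 in soxS, and 0 were lower. In appY 0 passed in limma (18 with an unadjusted p under 0.05). With median scaling the numbers were 0 in appY, 58 in arcA, 29 in fnr, 38 in arcAfnr, 1 in oxyR and 57 in soxS, and with the deposited values 2, 35, 9, 1, 1 and 50. Of 2118 intergenic probe sets, 110 were higher in appY, 46 in arcA, 124 in fnr, 76 in arcAfnr, 178 in oxyR and 29 in soxS, more than were lower in each strain, except that with the deposited values arcAfnr had 55 higher and 66 lower. Median scaling gave 173, 152, 193, 79, 243 and 111 higher, and the deposited values 166, 27, 79, 55, 254 and 31. The cause was not tested.

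The iron acquisition genes were higher in appY, fnr, arcAfnr and oxyR, and array scaling, loss of the iron regulator Fur and a difference in the cultures were weighed. The lowest median of the list over these 4 strains was 1.31 with the other scalings, so scaling did not make the pattern. The lowest log2 change of the fur transcript was -0.29 (in appY, adjusted p = 0.0786), so a lost transcript did not either, while the activity of the protein was not measured. The 12 arrays lay at 1.02 or above and the other 9 at 0.53 or below; a batch of medium or an iron supply that differed between cultures could give this, and so could the deletions, and the data cannot tell them apart.

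The third appY array differed from the other appY arrays by over 1 on the log2 scale in 362 genes, and an array of another strain, array scaling and the state of the culture were weighed. On it the genes deleted in arcA, fnr, oxyR and soxS, and the iron genes against wild, lay at least 1.16 above the highest array of those strains, which an array of another strain would not show. Of the 362 genes 90.6% differed by as much with both other scalings. All 9 oxygen lists lay outside the middle 95% of random lists in the direction named, as did 11 of the 18 other lists in either direction (arginine synthesis -2.57, acid resistance 1.87), with aerobic respiration lower (cyo -4.94) and anaerobic metabolism higher (hydrogenase 1 2.31), so less oxygen or a later growth stage at harvest may explain it. These 2 states were not separated.

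For the comparisons of 3 with 3 arrays, 10 splits are too few for a share under 0.05. The real split gave 470 genes for appY, 70 for arcA, 403 for fnr, 643 for oxyR, 107 for soxS and 223 for arcAfnr against arcA, where the highest other split gave 0, and 399 for arcAfnr and 51 for arcAfnr against fnr, where it gave 1. Of 100 regroupings of the 21 arrays 1, the real one, gave as many genes for a difference in any strain (985, highest other 1). That share holds only if all 21 arrays could be exchanged freely. The labels do not say that the samples of a strain were separate cultures, so differences between cultures are not excluded. For the overlap between strains 1 also gave as many (522, highest other 1), but the regroupings had few genes to share, so this does not test the overlap.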

How the results depend on the processing

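Array weights and the fits with the third appY array left out of the spread or of the estimated correlation were chosen only after the result was seen. Over the planned and added alternatives other than leaving out 1 array, 4760 tests of named genes gave the same result, 139 a stronger and 286 a weaker one, with 0 reversed in direction; for lists the numbers were 713, 19, 146 and 4. With 1 array left out they were 2478, 53, 505 and 0 for genes and 467, 0, 53 and 2 for lists. Targeted genes stayed as they were in 80 tests, with 1 stronger. The reversed lists were nuo in appY (adjusted p = 0.592 without appY 3, and 0.873 with an estimated correlation and appY 3 left out) and acid and fat oxidation in appY (0.388 and 0.68). Without appY 2 these lists kept their direction and passed (0.00138 and 1.92e-05). Their falls in appY rested on appY 3, where the nuo median against wild was -0.84, beside 0.01 and -0.07 on appY 1 and 2. For acid and fat oxidation these medians were -1.08, -0.05 and 0.02. The cyo list reversed in the interaction (0.0193 with only the strains compared, 0.0141 with the third appY array left out of the spread). The cause of the cyo reversal was not tested.

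With the third appY array left out of the spread, the number of genes was 286 for arcA, 820 for fnr, 681 for arcAfnr, 984 for oxyR, 250 for soxS, 424 for arcAfnr against arcA, 295 for arcAfnr against fnr and 119 for the interaction. Array weights gave 214 for appY, 576 for arcA, 849 for fnr, 691 for arcAfnr, 1104 for oxyR, 175 for soxS, 773 for arcAfnr against arcA, 429 for arcAfnr against fnr, 340 for the interaction, 1839 for any strain and 929 for the overlap. A fit with only the strains compared gave 23 for appY, 17 for soxS, 138 for arcAfnr against fnr and 88 for the interaction.

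The deposited values gave 119 genes for arcA and 81 for arcAfnr against fnr. Median scaling gave 93 for arcAfnr against fnr and 4 for the interaction, the floor at the 25th percentile 79 and 46. A spread without trend gave 1 gene for the interaction. A block for the replicate number gave 0 there in limma (668 genes had an unadjusted p under 0.05 without the block). Arrays with the same number were not paired: the mean correlation of their residuals was -0.007 over 63 pairs, and 0.003 for other numbers.

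Leaving out 1 array gave, as lowest and highest counts, 170 (without wild 3) and 780 (appY 1) for appY, 17 (arcA 3) and 98 (arcA 2) for arcA and 191 (fnr 3) and 354 (wild 1) for fnr. They were 187 (arcAfnr 2) and 363 (wild 1) for arcAfnr, 375 (oxyR 2) and 571 (wild 1) for oxyR and 48 (wild 3) and 105 (wild 1) for soxS. For the other results they were 128 (arcAfnr 2) and 215 (arcA 2) for arcAfnr against arcA, 12 (arcAfnr 2) and 44 (fnr 2) for arcAfnr against fnr, 0 (arcA 1) and 44 (arcA 2) for the interaction, 742 (oxyR 2) and 1353 (appY 3) for any strain, and 262 (wild 3) and 847 (appY 3) for the overlap. The values are signal over an unknown background, which limits fold changes of dim genes.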

Other observations

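The iron-sparing test and the genes named here were chosen only after the result was seen.

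All 4 genes of the nrdHIEF operon, for the manganese-dependent ribonucleotide reductase, rose in appY (1.93 to 3.90), fnr (2.87 to 4.86), arcAfnr (3.12 to 4.96) and oxyR (3.32 to 5.43), and passed there in every fit without 1 array, and 3 of them rose in soxS. The 6 suf genes, for building iron-sulfur clusters, rose in fnr (1.24 to 1.59), arcAfnr (1.38 to 1.87) and oxyR (1.82 to 2.16), and with all arrays 4 of them passed in appY and 1 in soxS. The iron storage gene ftnA fell by 0.88 ± 0.13 in appY, 0.92 ± 0.13 in fnr, 0.83 ± 0.13 in arcAfnr and 1.22 ± 0.13 in oxyR. The antigen 43 gene flu was higher in oxyR (2.38 ± 0.12) and lower in appY (-2.41 ± 0.12), fnr (-0.96 ± 0.12), arcAfnr (-1.09 ± 0.12) and soxS (-0.70 ± 0.12).

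Other operons moved in oxyR. The 4 dipeptide transporter genes of the dpp operon fell there (-1.76 to -1.16) and in arcAfnr (-1.50 to -0.82), the 6 genes of the cus region fell (-3.30 to -0.68), and 5 thiamine synthesis genes rose (0.58 to 0.96), each in every fit without 1 array. With all arrays the 4 dpp genes also fell in fnr (-1.01 to -0.58, 3 of them in every such fit), 4 cus genes passed as lower in fnr and 1 in appY, and 4 thiamine genes passed as higher in arcAfnr. The aromatic amino acid genes aroF, tyrA and pheA rose (0.69 to 1.60).

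Iron-sparing repression, in which the small RNA RyhB lowers messages for iron-using proteins, may account for the falls of sodB in fnr, arcAfnr and oxyR and of the nuo genes (2 of 13 in fnr, or 11 with the third appY array left out of the spread, 13 in arcAfnr and 13 in oxyR). The gene fumA fell in oxyR but did not pass in fnr (-0.97, adjusted p = 0.187) or arcAfnr (-1.14, adjusted p = 0.133). A list of 17 other genes, taken as lowered by RyhB without a check here, was set against 10000 random lists matched on level. Its median lay at or below the 0.02 percentile in all 3 strains, with 4 of 17 members lower in fnr, 5 in arcAfnr and 6 in oxyR. It lay at the 0 percentile in appY (9 of 17 lower), where the third array stands apart, at 91.76 in arcA and at 29.74 in soxS. With the 11 members on no other list it lay at 0.17 in fnr, 0.05 in arcAfnr and 0.05 in oxyR. Random lists do not match that 6 members lie in the isc operon, none of which passed in fnr or arcAfnr. Without them the other 11 lay at the 0 percentile in fnr, arcAfnr and oxyR, but also at 0.84 in soxS, where 0 members passed, so the shift was not confined to the 3 strains. These 11 include dmsA, frdA and nirB, which are on the anaerobic respiration list tied to Fnr. The 5 members outside the isc operon and on no other list lay at 0.05 in fnr, 0.06 in arcAfnr, 0.01 in oxyR and 0.32 in soxS. The level of RyhB itself was not analysed here, and a direct loss of iron was not separated from a change in Fur activity.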
